A study of Schizosaccharomyces pombe with 4 samples.

How the data were processed

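RNA was sequenced from 2 wild-type and 2 delta4dus samples of the fission yeast Schizosaccharomyces pombe, grown in rich YES medium at 32 °C to an optical density (595 nm) near 0.5. Per the labels' protocols, total RNA came from a hot phenol extraction of 50 mL of culture, 1 µg of it was depleted of ribosomal RNA, its RNA integrity number was above 8.5, and 125 ng of depleted RNA entered a strand-preserving Illumina library protocol. The labels give each library a genotype and a replicate number from 1 to 2, and do not say whether replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

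The deposited count table holds raw read counts for 7049 genes in 4 libraries, and no count column was left without a sample. Per the submitters' processing notes, the reads were trimmed with Trimmomatic 0.36, aligned with TopHat2 to the ASM294v2 build and counted with featureCounts; the counting options for strand, multiply mapped reads and overlapping genes are not given in the sources used here. The values were therefore checked. The 3 copies of the large ribosomal RNA gene differed by at most 0.513% within a library, so a read that maps to several copies was counted at each of them. In 351 non-coding RNA genes lying at least 90% inside 1 coding gene of the opposite strand, the median number of reads per base was 0.0815 of that of the coding gene. Counting without strand would give a value near 1 or above. A small nucleolar RNA gene and the non-coding RNA gene that overlaps it, SPSNORNA.20 and SPNCRNA.906, held 236941 and 237040 counts in the first wild-type library, so reads of overlapping features were counted at both. Near-identical copies and genes overlapping on one strand are reported as uncertain for these reasons.

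The second table, deposited by the authors, holds their own comparison of delta4dus with wild-type: a mean normalised signal per gene, a log2 fold change with its standard error, a test score (the fold change over its error) and p-values. DESeq2 is named for it in the submitters' processing notes. The authors' deposited table has 7000 rows, and the 49 ribosomal RNA genes of the count table have none.

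Library totals were 289767027 and 264948323 counts in wild-type and 435405178 and 495098038 in delta4dus. Without ribosomal RNA genes they were 44356401, 40203853, 59273688 and 46160896 in the same order. Reads have no molecular identifiers, so errors from counting alone would be too small, and the spread between libraries sets the precision.

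The count test was edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its defaults (a minimum count of 10 and a minimum total of 15), which left 6813 of 7049. Libraries were scaled by TMM, with factors of 1.227 and 1.125 for wild-type and 1.094 and 0.662 for delta4dus. A robust quasi-likelihood model with the genotype as its term was fitted to all libraries (2 residual degrees of freedom), the test was two-sided, and p was adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called at an adjusted p under 0.05, and 2-fold calls also needed a log2 fold change of at least 1 in size. Normalised counts are counts divided by the TMM-based relative library size, standard errors of log2 fold changes come from the quasi-likelihood F, and intervals are 95% intervals. The test, the 29 gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

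Gene lists were tested with camera (limma 3.58.1) on the same fit with a preset correlation of 0.01, adjusted over the 29 lists, each with at least 3 tested members. The result of 1 list is not reported here. Camera asks whether a list differs from the other genes. Camera with an estimated correlation and fry were run beside it. By the rule for named genes, the text names the 4 deleted genes, coding genes past the threshold (up to 10 per direction) with a mean of at least 1 CPM and non-overlapping groups, up to 3 non-coding genes per direction by the same criteria, up to 4 called members per list, the 4 tubulin genes and the genes next to the deleted loci. Where no gene passed in a direction, the 3 with the smallest p were named as not passing. Genes named as list examples or from the authors' deposited table were chosen after their values were seen.

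Symbols and products came from the RefSeq annotation of ASM294v3, matched by systematic identifier for 6844 of 7049 genes; coordinates are those of the deposited table (ASM294v2). Simulated counts for 6813 genes, drawn from the real means, spreads and library sizes, tested the fit of delta4dus against wild-type. edgeR recovered 50.7% of 67 genes changed 1.5-fold, 83.6% of 67 changed 2-fold and 92.4% of 66 changed 4-fold. It also called 34 of 6613 unchanged genes, which were 18.4% of its calls, and DESeq2 called 57 unchanged genes, 26.6% of its calls. The share of false calls in the simulation was thus above the nominal level in both. More genes were called there than in the data, where edgeR called 5, so the adjusted threshold was looser. The simulated libraries also lacked shared deviations. The recovered shares therefore need not hold in the data, where mfm2, at a log2 fold change of −1.50, had an edgeR adjusted p of 0.231. Of 1 simulated list raised 1.5-fold, camera with the preset correlation made the call, whereas camera with an estimated correlation and fry did not. None of them called any of 20 unchanged lists. The simulated genes were drawn independently. In the lists that camera called in the data, the estimated correlation ranged from −0.111 (M mating type) to 0.903 (Tf2 retrotransposons). The simulation therefore does not show how often camera calls unchanged lists of correlated genes.

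The alternatives were RLE scaling, library totals alone, other low-count filters, coding genes alone, DESeq2 1.42.0, the replicate number as a block and each library left out in turn. The fits without the 49 ribosomal RNA genes were added after the data were seen. Figures were drawn with matplotlib.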

Results

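The series measured transcript levels in Schizosaccharomyces pombe by RNA sequencing after ribosomal RNA depletion, in a wild-type strain and in delta4dus, a strain named for the deletion of dus1, dus2, dus3 and dus4. These genes encode the dihydrouridine synthases, enzymes that reduce uridine to dihydrouridine in RNA. There were 2 libraries per genotype, with 264948323 to 495098038 counts each. Ribosomal RNA genes took 84.69% and 84.83% of the counts in the wild-type libraries and 86.39% and 90.68% in delta4dus, which left 40203853 to 59273688 counts per library for the other genes. The comparison asks how transcript levels differ between the 2 strains.

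The deleted genes were examined first. Reads at dus1, dus2 and dus3 fell in delta4dus, by 14.5-fold, 7.75-fold and 2.95-fold. Reads at dus4 were lower in both delta4dus libraries but did not pass the test. The normalised read count of dus1 (SPBC36B7.04, chromosome II, 2389462 to 2390997, plus strand) was 2272 ± 87.4 in wild-type and 158 ± 35.0 in delta4dus (SD, n = 2 libraries each). That of dus2 (SPBC1709.06, chromosome II, 1108615 to 1110598, plus strand) was 2276 ± 99.2 and 294 ± 11.3, and that of dus3 (SPAC16.04, chromosome I, 4429631 to 4431741, plus strand) was 3880 ± 17.4 and 1314 ± 38.0. The log2 fold changes were −3.86 (SE 0.158, adjusted p = 0.00418), −2.95 (SE 0.0761, adjusted p = 0.000224) and −1.56 (SE 0.0550, adjusted p = 0.000818) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. For dus4 (SPCC777.15, chromosome III, 1624612 to 1626267, plus strand) the counts were 532 and 562 in wild-type and 309 and 153 in delta4dus. Its log2 fold change of −1.23 had a 95% interval from −2.21 to −0.25 and an adjusted p of 0.626 by edgeR (unadjusted p = 0.0246). Without delta4dus replicate 1 it was −1.84, and without replicate 2 −0.82.

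The reads that remained in delta4dus came to 6.95% of the wild-type level for dus1, 12.9% for dus2, 33.9% for dus3 and 42.2% for dus4. In the ASM294v3 annotation, untranslated regions make up 15.6%, 10.7%, 9.91% and 39.4% of these transcripts in the same order. The extent of each deletion is not given in the sources used here, and the counts cover the whole annotated gene, so they do not show which part of a gene the remaining reads came from. Without the second wild-type library the call of dus1 was lost (adjusted p = 0.0528, log2 fold change −3.82), and with library totals in place of TMM that of dus3 was lost (adjusted p = 0.0925, log2 fold change −1.99), both by edgeR.

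**Figure D1:**
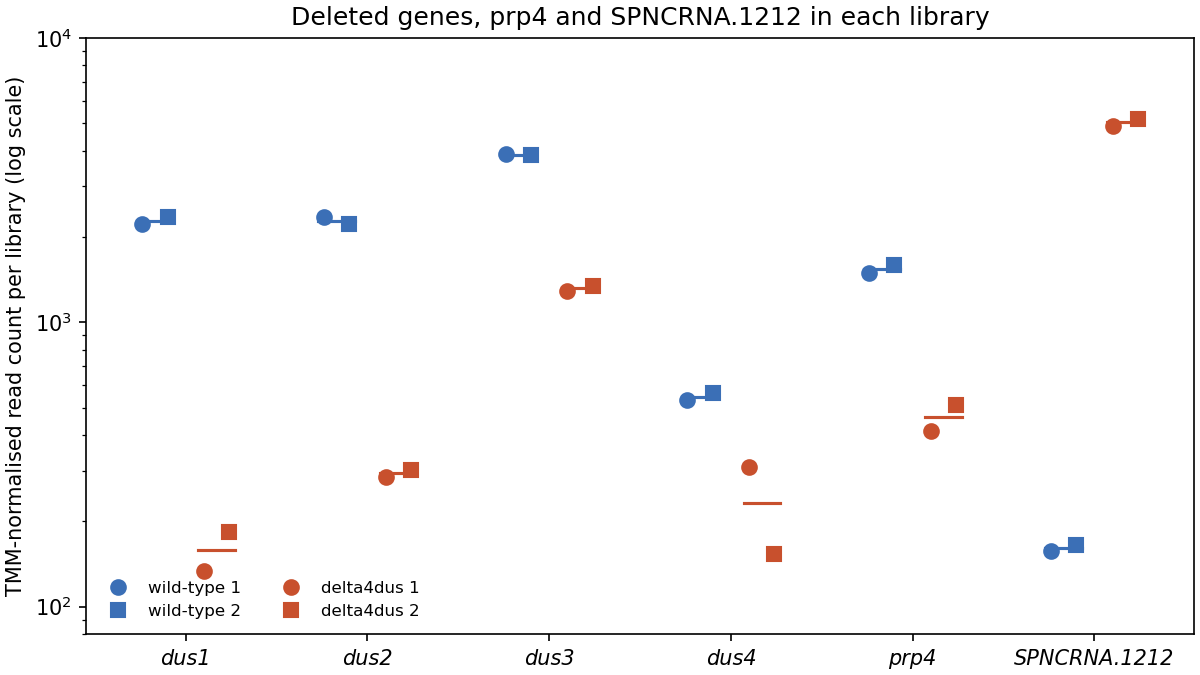
TMM-normalised read counts (log axis) of the 4 deleted genes, prp4 and SPNCRNA.1212 in each library; blue, wild-type; orange, delta4dus; circles and squares, replicates 1 and 2; bars, means of 2 libraries. The 2 genotypes do not overlap at any of the genes, and the delta4dus libraries are farthest apart at dus4, with 309 and 153.

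Apart from the deleted genes, edgeR called 2 genes, and both lie beside dus4. The non-coding RNA gene SPNCRNA.1212 rose 31.3-fold, and prp4, which encodes a protein kinase of pre-mRNA splicing, fell 3.33-fold. SPNCRNA.1212 (chromosome III, 1622525 to 1625429, minus strand) runs antisense over nearly all of prp4 and into the annotated 5′ part of dus4. Its normalised count was 161 ± 5.31 in wild-type and 5038 ± 213 in delta4dus (SD, n = 2 libraries each), a log2 fold change of 4.97 (SE 0.0732, adjusted p = 2.1e-05, edgeR). The gene prp4 (SPCC777.14, chromosome III, 1622498 to 1624475, plus strand) ends upstream of dus4 on the same strand. Its count was 1537 ± 75.8 in wild-type and 463 ± 68.0 in delta4dus, a log2 fold change of −1.73 (SE 0.120, adjusted p = 0.0196, edgeR). Without either of the wild-type libraries prp4 was no longer called (edgeR adjusted p = 0.128 without replicate 1 and 0.199 without replicate 2), while its log2 fold change stayed at −1.78 and −1.68. The downstream neighbour ekc1, a phosphatase regulatory subunit gene whose end overlaps dus4 on the other strand, had a log2 fold change of 0.26 (adjusted p = 0.52 by edgeR, 0.00286 by DESeq2).

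**Figure D2:**
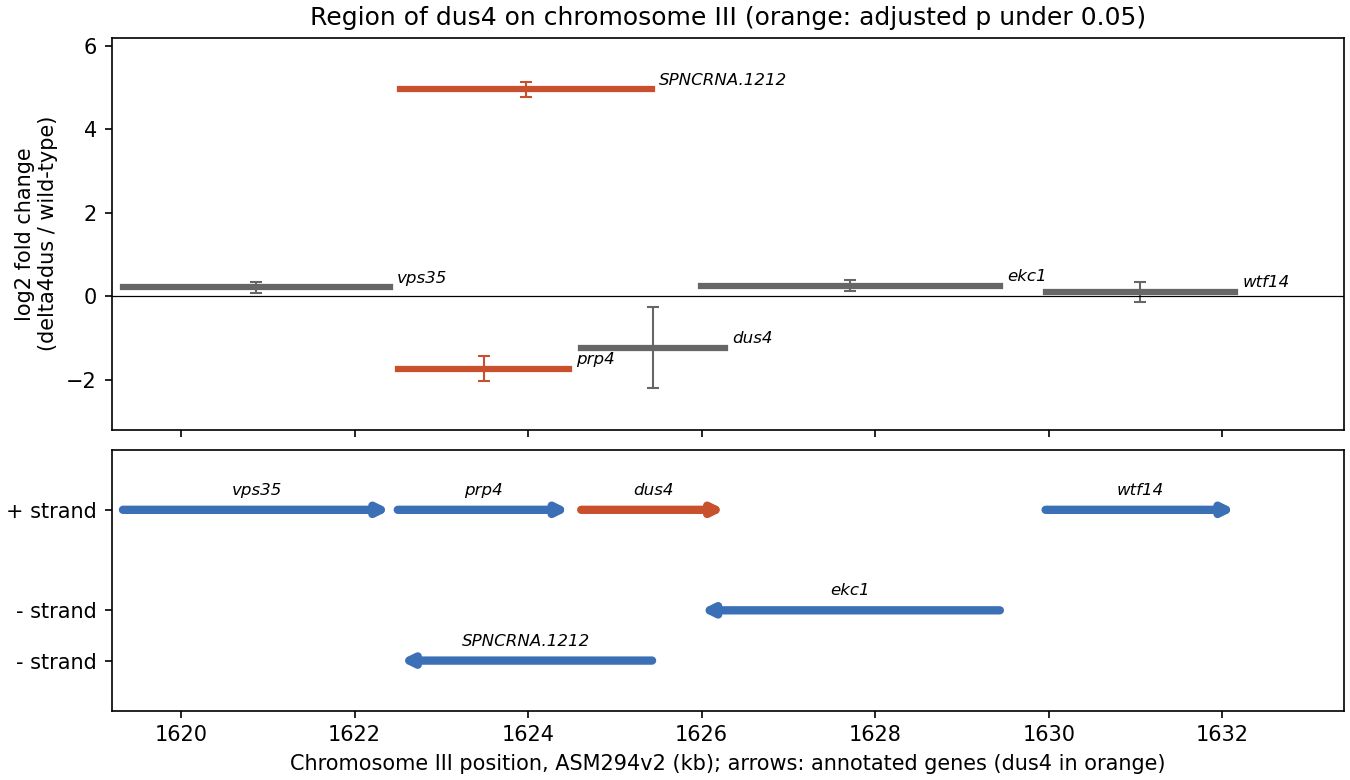
Region around dus4 on chromosome III (ASM294v2, kb). The upper panel gives the log2 fold change of each gene (delta4dus over wild-type, bars span the gene, whiskers are 95% intervals, orange marks adjusted p under 0.05), and the lower panel gives gene positions and strands: SPNCRNA.1212 at 4.97 and prp4 at −1.73 lie on opposite strands of the same segment.

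Over the genome, 5 of 6813 genes tested were called, 1 higher and 4 lower, and all 5 differed by at least 2-fold. With RLE scaling in place of TMM there were 2 higher and 4 lower; the added gene was SPATRNACYS.02, a tRNA-Cys gene with an adjusted p of 0.0501 under TMM. Leaving out the second wild-type library left 3 calls. At an unadjusted p under 0.05 there were 516 genes (242 higher, 274 lower), where 341 would be expected by chance. The median size of the log2 fold change was 0.0862, and 92.9% of genes lay within 0.5 of 0. The groups did not overlap in 38.7% of genes, against 33.3% by chance if the 4 libraries varied alike and independently. Same-numbered libraries deviated together (Pearson 0.635 across genes), so the share by chance need not be 33.3%. DESeq2 called 52 genes, 28 higher and 24 lower. The replicate number as a block in edgeR gave 825 calls, 432 higher and 393 lower, but the labels do not say that the numbers mark pairs.

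No coding gene passed in the upward direction. The 3 with the smallest p were ura2 (dihydroorotase of pyrimidine synthesis; log2 fold change 0.69, edgeR adjusted p = 0.231), SPCC777.02 (0.34, 0.484) and abc1 (0.28, 0.484). Of these, ura2 lies 673 bases from dus3. Of genes not annotated as coding, none passed in the downward direction. The 3 with the smallest p were SPNCRNA.1071 (−0.76, edgeR adjusted p = 0.188), which overlaps the heat shock gene hsp9 on the same strand, SPMTR.04 (−0.62, 0.484), which has no match in the annotation and shares nearly all its reads with the coding genes mat1-Mc and mat3-Mc, and SPNCRNA.742 (−0.59, 0.484), which overlaps met26. DESeq2 called all 6 of these genes.

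The tubulin genes did not pass the test. The log2 fold change was −0.07 (95% interval −0.21 to 0.08) for nda2, an alpha-tubulin gene, 0.01 (−0.12 to 0.14) for atb2, the other alpha-tubulin gene, 0.03 (−0.12 to 0.17) for nda3, beta-tubulin, and −0.02 (−0.20 to 0.16) for gtb1, gamma-tubulin. The value of nda2 was negative under every alternative. The signs of the other 3 changed without single libraries, and atb2 and nda3 were also negative with library totals alone, where the median of all genes was also shifted by −0.42.

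**Figure D3:**
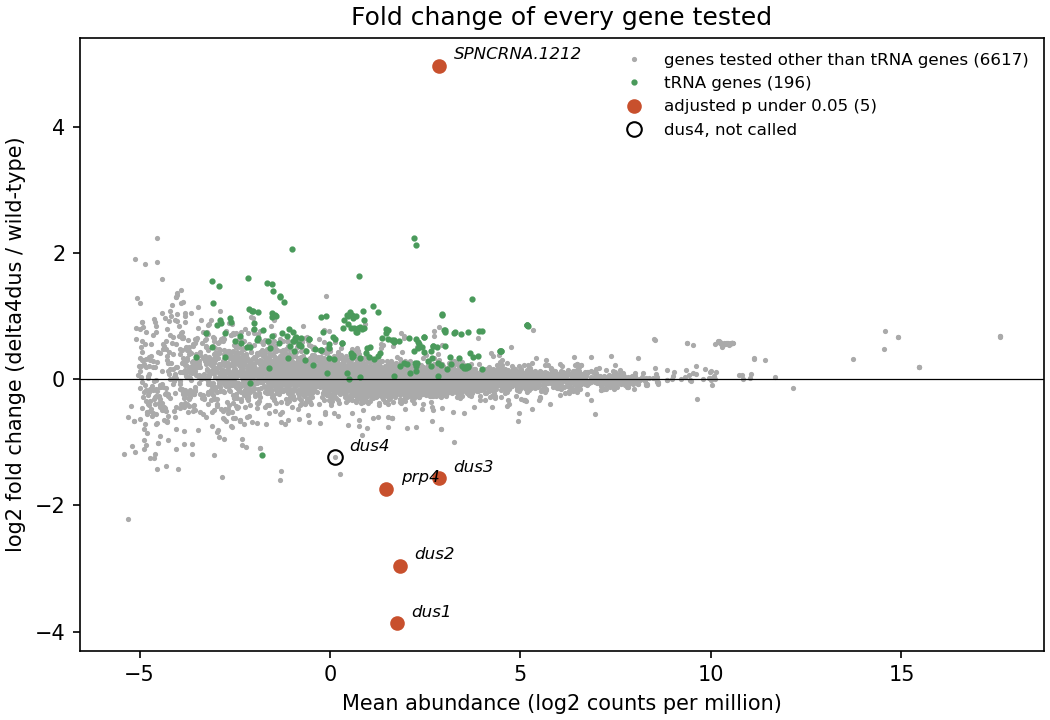
Log2 fold change (delta4dus over wild-type) against mean abundance (log2 CPM) for the 6813 genes tested; green, 196 tRNA genes; orange, the 5 called genes; open circle, dus4. SPNCRNA.1212 stands at 4.97 and dus1 at −3.86, and nearly all tRNA genes lie above 0.

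Of the 29 gene lists, 11 passed with camera's preset correlation, 7 higher and 4 lower than the other genes. None passed with an estimated correlation: the adjusted p was 0.506 with an estimated correlation for each of the 11. Where a list is said below to rise or fall, the call came from the preset correlation and was lost with an estimated one. By fry's directional test 2 lists passed, the genes next to a dus gene (adjusted p = 0.0175) and the tRNA modification enzymes other than Dus (adjusted p = 0.000238, lower). The latter list had an adjusted p of 0.148 by camera and a small median log2 fold change of −0.04. Of its 17 genes, 13 lay below 0 and none passed when adjusted over the list alone.

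The genes next to a dus gene rose as a list (camera adjusted p = 2.91e-08). All 8 had a positive log2 fold change, with a median of 0.24, and 1 passed over all genes and 4 when adjusted over the list alone. The list holds the nearest gene on each side and so leaves out prp4, which lies 137 bases from dus4 and fell. Besides SPNCRNA.1212 and ekc1, the values were 0.50 for pib1 (ubiquitin ligase; adjusted p = 0.484 by edgeR, 0.0219 by DESeq2) and 0.22 for sec63 (protein translocation), the neighbours of dus1. They were 0.10 for sks2 (ribosome-associated chaperone) and 0.08 for erg27 (sterol synthesis), the neighbours of dus2, and 0.06 for sfp1 and 0.75 for SPNCRNA.247, those of dus3. SPNCRNA.247 had 5 to 15 counts per library, and its value was 0.27 without wild-type replicate 1 and 1.36 without replicate 2. With library totals alone, sec63, ekc1, sks2, erg27 and sfp1 were negative, and all lay above the shifted median of all genes.

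Transfer RNA genes rose together as a list by camera with the preset correlation (adjusted p = 1.5e-29), with 194 of 196 above 0 and a median log2 fold change of 0.62. Their estimated correlation was 0.632, and with it camera gave an unadjusted p of 0.213. Normalised tRNA totals overlapped between the genotypes, at 201340 and 276210 in wild-type and 255100 and 456140 in delta4dus. None passed over all genes and 1 passed when adjusted over the list alone. With counts summed by isotype, both delta4dus libraries exceeded both wild-type libraries in 8 of 20 nuclear isotypes. Transfer RNA-Cys had the largest rise among these sums, from 192 ± 11.7 to 627 ± 81.1 (SD, n = 2 libraries each; log2 fold change 1.70, SE 0.148), with an adjusted p of 0.027 by edgeR, followed by tRNA-Val (log2 fold change 1.44, SE 0.521, adjusted p = 0.673, edgeR) and tRNA-Trp (1.30, SE 0.253, adjusted p = 0.422). Adjusted over the 40 nuclear and mitochondrial isotypes alone, 4 passed, among them tRNA-Cys (0.000973) and tRNA-Trp (0.0245). The sums were tested after the data were seen. Other structured RNA differed between the libraries too: normalised counts of 5S ribosomal RNA were 8213000 and 18523000 in the wild-type libraries and 9775700 and 28983000 in delta4dus, so wild-type replicate 2 lay above delta4dus replicate 1. The mitochondrial genome list rose (camera adjusted p = 5.35e-05), with its 25 tRNA genes all above 0 (median 0.33) and 4 of its 11 other genes above 0 (median −0.08).

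**Figure D4:**
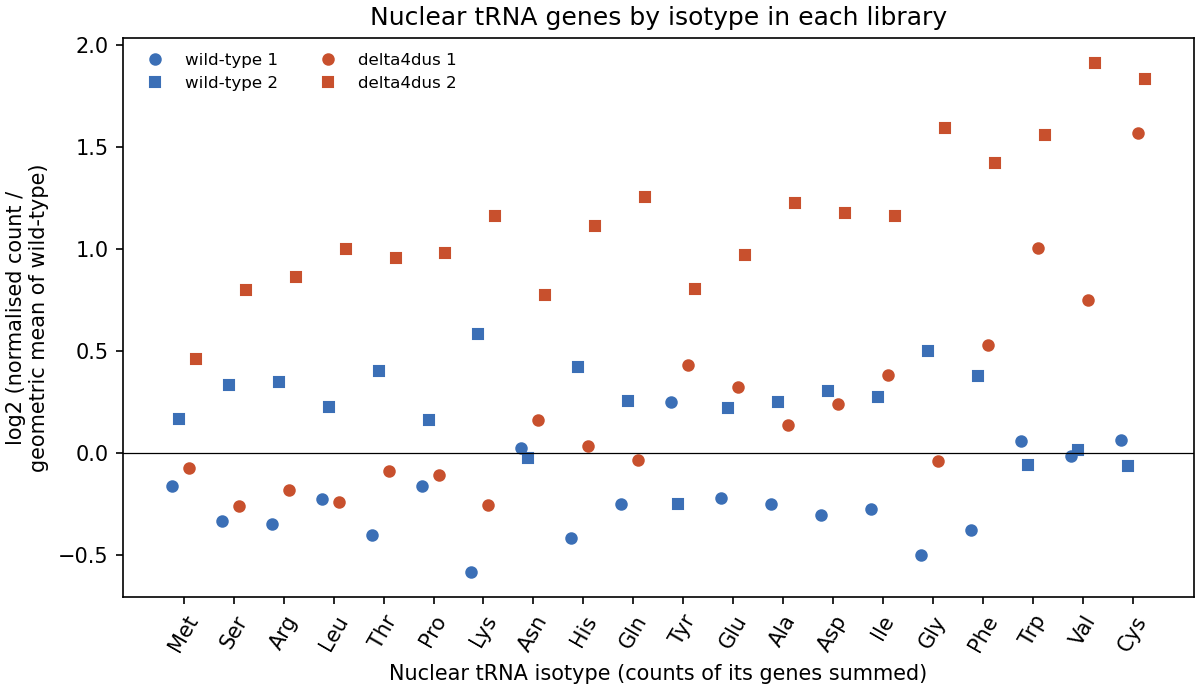
Normalised counts of nuclear tRNA genes summed by isotype, as log2 ratios to the geometric mean of the wild-type libraries; blue, wild-type; orange, delta4dus; circles and squares, replicates 1 and 2. The second delta4dus library is the highest for every isotype, and both delta4dus libraries lie above both wild-type libraries in 8 of 20, including tRNA-Cys.

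Among lists of coding genes, the mating and nitrogen starvation genes fell (camera adjusted p = 0.00252; 17 of 23 below 0, median −0.22), as did the M mating type genes (adjusted p = 0.000754; 6 of 8 below 0, median −0.53), 7 of which are also in the first list. No member of either passed over all genes; adjusted over the list alone, 2 were lower and 1 higher in the first, and 3 were lower and 1 higher in the second. The values were −1.50 for mfm2, a precursor gene of the M-factor pheromone, −0.72 for mam2, the receptor for P-factor, and −0.61 for mat1-Mc, a mating-type regulator. The P mating type genes did not pass (camera adjusted p = 0.881), but only 4 were tested, as mat1-Pc and mat1-Pi were not matched. Without the first wild-type library the mating list was no longer called (adjusted p = 0.0564).

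Histone genes fell (camera adjusted p = 0.000885), with 10 of 10 below 0, a median of −0.16 and 1 lower over the list alone. Histone H4 gene hhf1 had a log2 fold change of −0.30 and H2A gene hta1 of −0.21. Mitochondrial ribosomal protein genes fell (camera adjusted p = 9.78e-06; 34 of 39 below 0, median −0.11, none over the list alone), with −0.31 for mrpl28 and −0.26 for mrpl1. The call of the histone list was lost without the first delta4dus library (adjusted p = 0.246).

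The Tf2 retrotransposons rose (camera adjusted p = 6.67e-11). All 13 copies lay above 0, with a median of 0.26 and 10 past the threshold over the list alone, but the copies share reads and are not independent. The nitrogen source list rose (adjusted p = 0.00129; 15 of 17 above 0, median 0.13, 1 over the list alone), with 0.78 for the amino acid transporter gene isp5, which was also in the mating list, 0.44 for put4, a proline transporter gene, and 0.33 for amt1, an ammonium transporter gene. The hexose transport and glucose repression list rose (adjusted p = 0.027; 10 of 16 above 0, median 0.14, none over the list alone), with 0.58 for inv1, invertase, and 0.29 for agl1, an alpha-glucosidase gene. The non-coding RNA genes rose (adjusted p = 2.67e-05; 884 of 1364 above 0, median 0.08), with SPNCRNA.1212 the 1 gene called. Leaving out a library ended the call of the nitrogen list (0.137 without delta4dus replicate 2), of the non-coding list (0.101 without delta4dus replicate 1) and of the hexose list (0.16 without wild-type replicate 1, 0.0623 and 0.176 without delta4dus replicates 1 and 2), all camera adjusted p. Library totals alone ended those of the nitrogen (0.0991) and hexose lists (0.224), and the replicate block ended that of the hexose list (0.123).

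The other lists did not pass in the main fit, and none of their genes passed over all genes. Camera's adjusted p was 0.0616 for the induced core stress genes, of which hsp9 (−0.67) passed over the list alone and the cation pump gene cta3 lay at 1.32. It was 0.0695 for the Pap1-dependent oxidative stress genes, with the same value for the cytosolic ribosomal proteins. It was 0.375 for small nucleolar and nuclear RNA genes and 0.477 for protein folding, for sterol synthesis, for tubulin and microtubule genes and for actin and cytokinesis. It was 0.567 for iron uptake, 0.579 for phosphate acquisition and for strain markers, 0.664 for the MBF list, 0.72 for meiosis and sporulation and for galactose and subtelomeric genes, and 0.805 for RNA surveillance. Some of these lists passed under single alternatives: without wild-type replicate 2 or without delta4dus replicate 1, the core stress genes (camera adjusted p = 0.00577 and 0.0186) and the small nucleolar and nuclear RNA genes (0.00108 and 0.00983), and without wild-type replicate 2 the Pap1-dependent genes (0.0283). Cytosolic ribosomal proteins passed with library totals alone (0.000322), without wild-type replicate 1 (0.0025) and without delta4dus replicate 2 (8.85e-08). Iron uptake passed with library totals alone (0.0438) and without either wild-type library (7.26e-07 without replicate 1; 0.00104 without replicate 2, in the opposite direction).

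The authors' deposited table called 49 genes at an adjusted p under 0.05, 26 higher and 23 lower, of which 13 differed by at least 2-fold. They were 31 coding genes (11 higher, 20 lower), 13 tRNA genes (all higher), 4 non-coding RNA genes and 1 other. Some of these calls appear to share reads. The called nuclear tRNA-Glu genes had near-equal counts, and the coding gene lcp1 overlaps SPATRNAGLU.01 on its strand. Counts were also near-equal among mat1-Mc, mat3-Mc and SPMTR.04, and between ftm5 and SPBPB2B2.19c. The 49 therefore stand for fewer distinct signals. All 5 genes called by edgeR were among the 49, and each of the 49 had the same sign and an unadjusted p under 0.05 in edgeR. DESeq2 without the 49 ribosomal RNA genes called the same 49, with log2 fold changes within 1.4e-05 of the deposited ones. In the authors' deposited table the log2 fold change was −1.50 for mfm2, −0.99 for SPAC27D7.09c, −0.66 for hsp9, 0.78 for isp5 and 1.32 for cta3.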

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

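The fits without ribosomal RNA genes were chosen after the data were seen, the others before. With edgeR, 5 genes differed. This count and that of 2-fold genes stayed within 1.5 times of it with RLE scaling, library totals alone (4), other filters, coding genes alone and without ribosomal RNA genes; dus2 was past the threshold under all 14 alternatives and dus4 under none of them (adjusted p from 0.0623 to 0.999). DESeq2 called 52 genes (14 by 2-fold), and 49 (13) without ribosomal RNA genes. The replicate number as a block gave 825 calls (49 by 2-fold), or 570 (38) without ribosomal RNA genes. The deviations of same-numbered libraries correlated (Pearson 0.635, Spearman 0.515 across genes), but with 2 numbers, and labels that tie them to no shared day, the numbers were not taken as pairs; the cause was not tested. Leaving out 1 library, which leaves a lone library assumed to vary like the other group, gave 3 to 5 calls and 3 to 5 by 2-fold, and 10 to 15 lists. Of the lists, 0 passed with an estimated correlation and 2 by fry, against 11, and the cause was not tested. Both tests missed the simulated list, whose genes were drawn independently, which does not settle the calls in lists of correlated genes.

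Signs changed for genes and lists not called in the main fit; of these genes, DESeq2 called SPCC777.02, abc1 and ekc1, and the block these and sec63. With library totals, the median of all genes was shifted to −0.42. There, the log2 fold change was −0.09 for SPCC777.02, −0.15 for abc1, −0.41 for atb2 and −0.40 for nda3. It was −0.35 for sfp1, −0.33 for sks2, −0.34 for erg27, −0.20 for sec63 and −0.17 for ekc1. Camera's direction turned for meiosis (adjusted p = 0.832), folding (0.832), tubulin (0.762) and strain markers (0.832). With coding genes alone it turned for P mating type (0.958), meiosis (0.958), MBF (0.958) and RNA surveillance (0.954).

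Without single libraries the ranges were −0.0088 to 0.0349 for atb2, −0.0912 to 0.04 for gtb1, −0.004 to 0.0547 for nda3, −0.0537 to 0.17 for sfp1 and −0.0122 to 0.18 for erg27. For the lists whose direction turned, the adjusted p ranged from 0.714 to 0.923 for P mating type, 0.223 to 0.869 for folding, 7.26e-07 to 0.816 for iron uptake, 8.85e-08 to 0.714 for cytosolic ribosomal proteins, 0.00108 to 0.374 for small RNA genes, 0.535 to 0.835 for RNA surveillance, 0.244 to 0.866 for galactose and subtelomeric genes and 0.315 to 0.869 for strain markers. Iron uptake turned from lower to higher than other genes without wild-type replicate 2 (0.00104), and was lower without wild-type replicate 1 (7.26e-07); the cause was not tested.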

Other observations

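Of the tests below, those of strand, of the clustering of calls and of tRNA were chosen after the result was seen. The 32 tested genes within 5 kb of a deleted locus hold 11 with an unadjusted p under 0.05 (edgeR), 34.4% against 7.52% of all tested genes other than the dus genes, and 22 of the 32 lie above 0. Near dus1 these include gcn2 (0.25), the gene of a kinase that phosphorylates the translation factor eIF2-alpha, and tlg1 (0.30), and near dus4 vps35 (0.21), a retromer gene. None of these 3, picked after their values were seen, passed the adjusted test.

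Beside dus4, prp4 was lower and SPNCRNA.1212 higher. Reads counted without regard to strand would move these 2 the same way, but prp4 lay at −1.73 with SPNCRNA.1212 at 4.97. The opposite signs are the pattern itself, so this is no separate test. Apart from dus genes, edgeR called no others, and 0.41% of 10000 random draws of 4 windows of 5 kb held as many. The 2 overlap, so this concerns the place of 1 locus. Of the authors' 44 other calls, 3 (ura2, pib1 and ekc1) lie within 5 kb of a dus gene, as many as in 0.16% of draws. Both draws were made after these genes had been seen beside dus genes, and both sets of calls come from the same 4 libraries. The draws therefore describe the clustering and do not decide against an effect with no relation to position. For all genes within 5 kb of the 4 loci, the median size of the log2 fold change over its error, without regard to sign, was 1.18 against 0.812 for all genes. It lay at the 94.95th percentile of 10000 draws (the 7.68th for genes 10 to 50 kb away). This leaves open whether the genes near the loci were affected as a set. In the main fit ura2, pib1 and ekc1 did not pass (edgeR adjusted p = 0.231, 0.484 and 0.52). By the bound set in advance (95 or less) the value of 94.95 counted against a cis effect and for an effect with no relation to position. The allowance for simulation error (0.22), within which the value falls on the bound, was chosen after the value was seen. An effect of the dus4 deletion in cis, such as antisense transcription that starts at the deletion, may account for prp4 and SPNCRNA.1212. It stays a hypothesis, since the structure of the locus was not examined.

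Summed by isotype, all 20 nuclear isotypes lay above 0, from 0.21 to 1.70, with a median log2 fold change of 0.638. A rise from a few isotypes with many copies was to give 0 or less. As 194 of 196 tRNA genes lay above 0, their sums could hardly lie elsewhere and are no separate evidence. The spread of 0.05 set for this median takes the isotypes as independent. The median was 0.358 between the libraries numbered 1, 0.844 between those numbered 2 and 0.503 between wild-type replicates 2 and 1. Whether counting a read at each near-identical copy accounts for the call of the set stayed open. The isotype sums gave p = 2.77e-15 by camera with the preset correlation of 0.01 but 0.147 with an estimated one. The correlation estimated for the tRNA genes was 0.632. A difference in structured RNA left in the libraries stays open for the isotypes as a set: delta4dus replicate 1 had less 5S ribosomal RNA than wild-type replicate 2 (log2 ratio −0.92), and over the 20 nuclear isotypes its median log2 ratio to that library was −0.17, as such carry-over would give. For tRNA-Cys the log2 ratio was 1.63 between the same libraries and −0.12 between the wild-type libraries, which carry-over that follows 5S ribosomal RNA would not give. This isotype was picked for its rise, with the genotypes already apart, so the ratio is no separate test. Carry-over that differs by isotype was not tested. Transfer RNA-Cys, which had the largest rise, was not alone. The same ratios were 1.065 and −0.12 for tRNA-Trp and 0.734 and 0.028 for tRNA-Val. Of the 20 nuclear isotypes, 8 lay higher and 12 lower in delta4dus replicate 1 than in wild-type replicate 2. The loss of the synthases, which act on tRNA, is a candidate explanation for tRNA-Cys, through its amount or through how the RNA is copied in library preparation, and neither was tested.

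In the authors' deposited table, 6 genes within 50 kb of the ends of the annotation of chromosomes I and II were called, all lower. Among 75 distinct subtelomeric units, with counts that agreed within 5% in every library merged, 45 lay below 0. Their median log2 fold change was −0.18, and 0 of 10000 expression-matched random sets had a lower one. Copies with near-identical counts therefore do not account for the shift. Reads shared in part could, since ftm1, ftm4 and ftm5 (−0.77, −0.76 and −0.79), with the same product name, were not merged. The random sets also took genes singly. The replicates differed more: the median log2 ratio was −0.25 between the wild-type libraries and −0.41 between the delta4dus libraries, against −0.09 between the genotypes on the same scale. By the bound set in advance this pointed to a difference between replicates, but a shift of the same sign in both genotypes largely cancels from the comparison, which was considered only after the values were seen. The genotypes and a difference between preparations therefore cannot be told apart for these genes, whose median ratio was −0.17 between the libraries numbered 1 and −0.07 between those numbered 2.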
